A study of Homo sapiens with 14 samples.

How the data were processed

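Bulk RNA-seq was analysed from 14 libraries of the cholangiocarcinoma lines HuCCT1 and RBE, each with 4 DMSO vehicle and 3 CB-5339 libraries (2 µM, 7 days; the labels give no duration for vehicle). Per the labels' protocols, RNA was column-purified with DNase treatment on the column, and libraries were sequenced on a NovaSeq instrument as 150-base paired ends with a target of 30 M reads each. The deposited unit is counts: the authors deposited a table of raw whole-number read counts per gene for each line, with 62700 Ensembl gene identifiers and 7 columns. The columns were assigned to samples through the sample descriptions, and 0 columns belonged to no sample. The submitters' processing notes name the build GRCh38 (hg38). The aligner, the counting tool, the annotation release, the library kit and the use of strand are not given in the sources used here, so reads of overlapping, antisense or near-identical genes cannot be told apart. Totals per library, from 1730092 to 5808162 counts, lie well below the stated read target, and how many reads went uncounted is not known.

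Gene symbols came from a name table that named all 62700 identifiers, 20357 of them by the identifier itself. Coordinates, gene types, lengths and GC content came from the GENCODE v29 annotation of GRCh38, which held 58207 of the identifiers. Length and GC content are those of the longest annotated transcript of a gene, which need not be the one expressed. Of 297 genes named by the rule below, 78 overlap another tested gene. Replicates within groups were compared by chi-square of their counts, and none were identical or within sampling noise.

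Genes were filtered with filterByExpr (minimum count 10, minimum total 15), scaled with TMM factors and tested with edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Each line was fitted alone, and the difference between the responses was fitted over all 14 libraries with 4 group means. Log2 fold changes are CB-5339 over vehicle, and the difference is RBE minus HuCCT1. The SE of a log2 fold change is its size divided by the root of its F statistic. CPM values in the text were computed from the counts with TMM-scaled library sizes, given as mean ± SD. Folds against a group with 0 counts use a floor of 3 counts over the group. Small changes were missed more often in simulated counts built on these libraries. There the test recovered 52.4% of 1.5-fold, 94.0% of 2-fold and 100% of 4-fold changes in HuCCT1 (12983 genes, 3.83% of calls false). For RBE the shares were 70%, 86.6% and 98.5% (13470 genes, 4.55% false), and for the difference 44.6%, 71.4% and 76.3% (14806 genes, 6.99% false). Few genes were changed in the simulation, with 183, 198 and 143 calls for HuCCT1, RBE and the difference. The real comparisons called 54.6%, 59.1% and 49.6% of genes, so the simulated shares need not hold for them. The common biological coefficient of variation was 6.94% in HuCCT1 and 6.87% in RBE.

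A set of 34 gene lists was fixed before the data were examined, and 1030 of 1032 members matched. They cover targets of ATF4 and PERK; ER chaperones, ER-associated degradation, VCP and its cofactors, proteasome, heat shock, autophagy and lysosome, and NRF2 genes; amino acid, cholesterol, fatty acid, glycolysis and nuclear oxidative phosphorylation genes and mitochondrially encoded mRNAs. They also cover G1/S, G2/M, DNA repair, p53, apoptosis, histone, MYC, ribosomal protein, immediate early, NF-kB, interferon, antigen presentation and senescence genes, and mesenchymal, epithelial, cholangiocyte, hepatocyte, fibroblast, endothelial and leukocyte markers. Lists with at least 5 measured members were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, each with Benjamini-Hochberg adjustment over the lists of one comparison. A member counts as risen or fallen by its adjusted p over all genes tested, and counts adjusted over the list alone are given where they differ.

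The genes named were set by a rule fixed before the data were examined. It takes VCP, then in each line the 8 largest rises and 8 largest falls among called genes with a mean of at least 10 CPM and no overlap between groups. It adds up to 4 members of each list with the smallest adjusted p, the 8 genes per direction called in both lines with the largest smaller change, and the 6 genes per direction with the largest differences between the lines. The mitochondrial rRNAs, MT-ATP8, MT-CO1, ISG15 and genes named as overlapping others are exceptions chosen after their values were seen. Genes on the Y chromosome and XIST were left out, and a few genes that the rule names are not reported here.

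Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, DESeq2-type size factors, library totals without TMM factors, no low-count filter, a filter of 1 CPM in at least 3 libraries, leaving out each library in turn, the replicate number as a block, leaving out mitochondrially encoded genes, all 14 libraries in one fit, a test against a 1.5-fold change, and an estimated correlation for the lists. The removal of GC and length trends and the thinning of counts to the smallest library were added after the data were seen. So were both scalings from nuclear genes, which replaced library totals in a test of the RBE mitochondrial list after its value was known, and the choice to print the counts without HuCCT1 CB-5339 replicate 1 and without RBE CB-5339 replicate 3.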

Results

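RNA was sequenced from HuCCT1 and RBE, established human cell lines derived from cholangiocarcinoma, a cancer of the bile duct. Cultures received 2 µM CB-5339, an inhibitor of the ATPase VCP, for 7 days, or its DMSO vehicle, for which the labels give no duration. VCP, also called p97, extracts ubiquitinated proteins from membranes and complexes so that the proteasome can degrade them. The series concerns VCP as a drug target in this cancer, and the RNA profiles address which transcripts differ between inhibited and vehicle cultures of each line. Each line had 4 vehicle and 3 CB-5339 libraries, 14 in all. The labels call them biological replicates without saying what was kept separate, so the p-values measure the spread between these samples, which may be technical in part.

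Total counts over genes were 3864881, 4469422, 5231156 and 5014451 in the HuCCT1 vehicle libraries and 1730092, 4464996 and 3265705 in the HuCCT1 CB-5339 libraries. In RBE they were 5423316, 5033987, 5808162 and 5486773 with vehicle and 4663089, 4443168 and 4771043 with CB-5339. The first principal component carried 72.8% of the variance in HuCCT1 and 78.8% in RBE and separated treated from vehicle libraries in both. A pair of libraries stood apart from their own group on the second component. HuCCT1 CB-5339 replicate 1, the shallowest library, scored 28.7 there against -14.7 and -15.3 for the other CB-5339 libraries. RBE CB-5339 replicate 3 scored -25.0 against 12.4 and 17.2, and it lay farthest from vehicle on the first component. No pair of replicates agreed within sampling noise: the chi-square per degree of freedom between replicates ran from 1.33 to 4.81.

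VCP itself moved in opposite directions. VCP (ENSG00000165280, chromosome 9, 35056064 to 35073249, GRCh38, protein-coding) was at 330 ± 17.1 CPM in HuCCT1 vehicle libraries (SD, n = 4) and 436 ± 24.3 with CB-5339 (SD, n = 3), a 1.32-fold rise (log2 0.40, SE 0.07, edgeR quasi-likelihood adjusted p = 1.9e-05). In RBE it fell from 226 ± 10.0 to 168 ± 2.31 CPM (log2 -0.42, SE 0.07, edgeR adjusted p = 4.5e-06). The responses differed between the lines (log2 -0.79, SE 0.10, edgeR adjusted p = 3.6e-09). Neither change within a line passed a test against a 1.5-fold change.

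**Figure D1:**
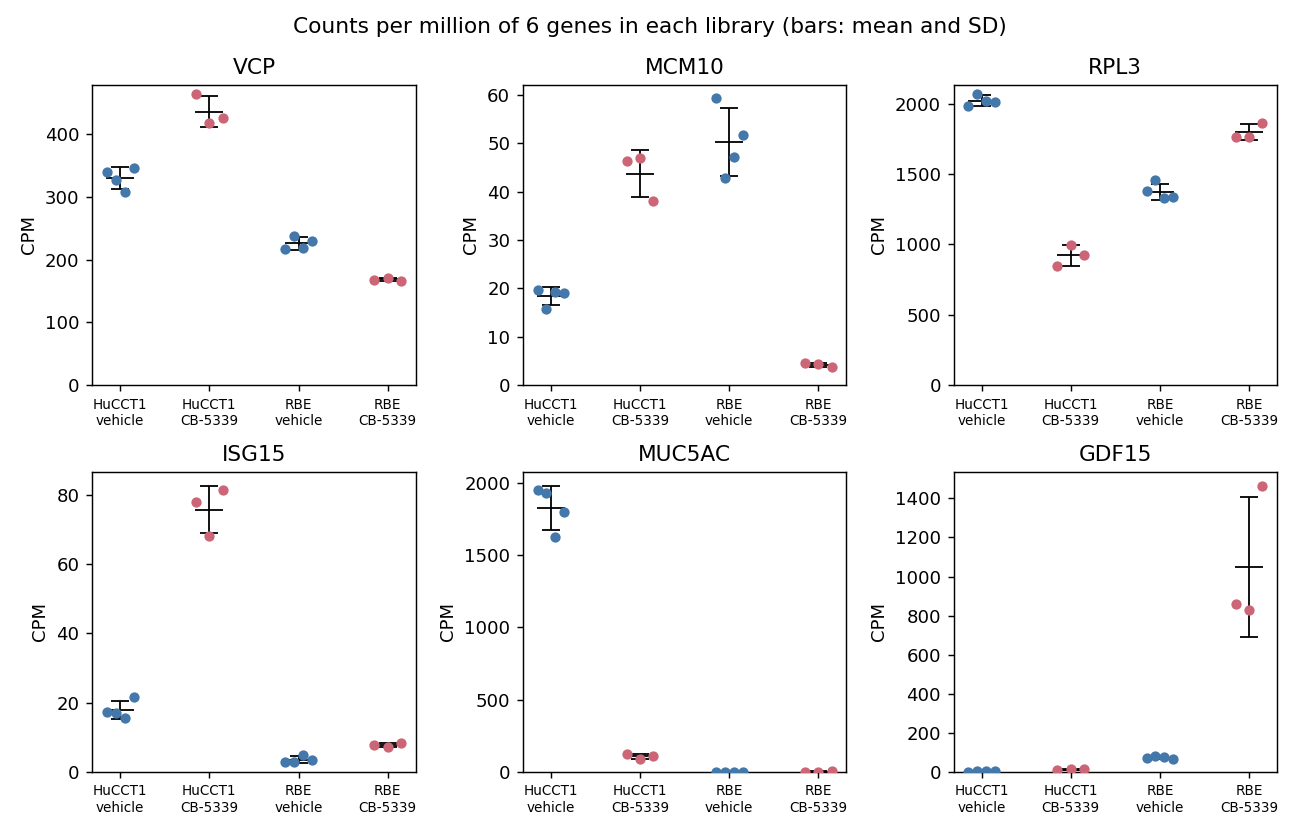
CPM (counts scaled to library size, y axes) of VCP, MCM10, RPL3, ISG15, MUC5AC and GDF15 in each library (points) of the 4 groups, with bars for the mean and SD. MCM10 went from 50.2 to 4.19 CPM with CB-5339 in RBE, RPL3 from 2020.4 to 921 CPM in HuCCT1, MUC5AC from 1827 to 106 CPM in HuCCT1, and GDF15 from 72.2 to 1049 CPM in RBE.

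In HuCCT1, interferon-induced genes and DNA replication genes rose with CB-5339, and ribosomal protein mRNAs and chaperones of the endoplasmic reticulum (ER) fell. With an estimated correlation the interferon call held (adjusted p = 0.0087), and those of the replication genes (adjusted p = 0.096), ribosomal proteins (adjusted p = 0.20) and ER chaperones (adjusted p = 0.096) were lost. MMP1 (ENSG00000196611, chromosome 11, 102789920 to 102798160), an interstitial collagenase, rose from 2.69 ± 1.67 to 888 ± 91.8 CPM, 317-fold (log2 8.31, SE 0.15, edgeR adjusted p = 8.0e-28). MUC5AC (ENSG00000215182, chromosome 11, 1157953 to 1201138), a gel-forming mucin, fell from 1827 ± 152 to 106 ± 16.6 CPM (log2 -4.13, SE 0.10, edgeR adjusted p = 4.8e-24). All 49 measured cytosolic ribosomal protein mRNAs fell.

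The other large rises in HuCCT1 included RNASE7, an antimicrobial ribonuclease, with 0 counts in the vehicle libraries and 279 in the CB-5339 libraries, at least 172-fold higher against a floor of 3 counts over the group. IL1RL1, the interleukin-33 receptor, rose by 5.74 on the log2 scale (SE 0.25), and SERPINB2, a plasminogen activator inhibitor, by 4.50 (SE 0.16). DUSP5, a nuclear phosphatase of ERK, rose by 3.86 (SE 0.14), the ectonucleotidase ENTPD3 by 3.52 (SE 0.11) and the elastase inhibitor PI3 by 3.39 (SE 0.14). RPLP0P2 rose by 4.63 (SE 0.20), but as a processed pseudogene of a ribosomal protein its reads are uncertain. Among the falls, the tight-junction gene CLDN2 went from 593 to 7 counts (log2 -5.48, SE 0.44), with -7.21 when CB-5339 replicate 2 was left out and -4.89 without CB-5339 replicate 3. ATOH8, a transcription factor, changed by -4.74 (SE 0.22), the mucin MUC6 by -4.25 (SE 0.31) and complement factor CFB by -3.69 (SE 0.16). NNMT, nicotinamide N-methyltransferase, changed by -3.49 (SE 0.13), and the transmembrane protein PLXDC2 by -3.28 (SE 0.24). UGT1A10 changed by -3.66 (SE 0.19), which is uncertain because UGT1A genes share their 3' exons. RNASE7, CLDN2, IL1RL1 and ENTPD3 overlap other measured genes (NDRG2, MORC4, IL18R1 and ENTPD3-AS1), and the strand used in counting is unknown.

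Of 45 genes of the G1/S transition and DNA replication, 39 rose in HuCCT1 and 6 did not pass, or 40 rose when adjusted over the list alone. The median was 0.79 on the log2 scale (camera adjusted p = 4.4e-16; adjusted p = 0.096 with an estimated correlation). RRM2, the ribonucleotide reductase subunit of S phase, rose by 1.43, the phosphatase CDC25A by 1.71, the origin-licensing factor CDC6 by 1.28 and the helicase subunit MCM4 by 1.05. Of 34 DNA damage repair genes 22 rose, 1 fell and 11 did not pass, with 23 and 1 adjusted over the list alone (median 0.53, camera adjusted p = 6.7e-06; adjusted p = 0.20 with an estimated correlation). BRCA1 rose by 0.99 and CLSPN, a checkpoint adaptor, by 1.24. Of 34 MYC targets and ribosome biogenesis genes 28 rose, 1 fell and 5 did not pass, with 29 and 1 adjusted over the list alone (median 0.71, camera adjusted p = 8.8e-13; adjusted p = 0.096 with an estimated correlation). They included MYC at 1.19, ornithine decarboxylase ODC1 at 1.60 and the ribosome assembly factor BOP1 at 1.24. Of 8 replication-dependent histone genes 6 rose and 2 did not pass, or 7 rose adjusted over the list alone (median 0.89, camera adjusted p = 0.027; adjusted p = 0.27 with an estimated correlation). That histone call was lost without vehicle replicate 2 (adjusted p = 0.053), vehicle replicate 4 (0.066) or CB-5339 replicate 2 (0.089), and with DESeq2 (0.052), no low-count filter (0.054), the replicate number as a block, which also leaves out vehicle replicate 4 (0.051), GC and length trends removed (0.071) or thinned counts (0.15).

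Interferon-induced genes rose, and their call held with an estimated correlation. Of 39 members 31 rose, 3 fell and 5 did not pass, with 32 and 3 adjusted over the list alone (median 1.28, camera adjusted p = 6.8e-21; adjusted p = 0.0087 with an estimated correlation). IFI6 rose by 3.39, IFI27 by 1.96, and OAS2 and OAS3, sensors of double-stranded RNA, by 2.53 and 2.31. The senescence secretory list rose as well: of 25 genes, 14 rose, 7 fell and 4 did not pass, with 14 and 8 adjusted over the list alone. Its median was 0.73 (camera adjusted p = 4.5e-12, and 0.027 with an estimated correlation). It also holds genes that are not secreted (LMNB1, CDKN1A, CDKN2A and CDKN2B) and shares cytokines such as IL1B and CCL20 with the NF-kB list. Of 25 immediate early genes 21 rose, 2 fell and 2 did not pass (median 1.19, camera adjusted p = 5.9e-14; adjusted p = 0.096 with an estimated correlation), with FOSL1, a subunit of AP-1, at 2.15 and the phosphatase DUSP1 at 2.53. Of 32 NF-kB and inflammatory cytokine genes 16 rose, 11 fell and 5 did not pass (median 0.26, camera adjusted p = 0.0092; adjusted p = 0.22 with an estimated correlation). IL1B rose by 2.93 and the chemokine CCL20 by 1.76. That NF-kB call was lost with DESeq2 (adjusted p = 0.052), with limma-voom (0.13) and with counts thinned to the smallest library (0.15), an alternative added after the data were seen.

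Protein homeostasis lists divided in HuCCT1. Of 33 proteasome subunits 24 rose, 1 fell and 8 did not pass, with 26 and 1 adjusted over the list alone (median 0.46, camera adjusted p = 1.7e-06; adjusted p = 0.30 with an estimated correlation). PSMD2 rose by 1.17 and PSMB2 by 1.00. Of 23 cytosolic heat shock genes 18 rose and 5 did not pass, or 19 rose adjusted over the list alone (median 0.51, camera adjusted p = 9.6e-07; adjusted p = 0.096 with an estimated correlation). HSPH1, a nucleotide exchange factor of HSP70, rose by 1.27, HSP90AA1 by 1.05 and the co-chaperone BAG3 by 1.03. In contrast, 21 of 27 ER chaperones and targets of ATF6 and XBP1 fell and 6 did not pass (median -0.70, camera adjusted p = 1.4e-10; adjusted p = 0.096 with an estimated correlation). HSP90B1 fell by 1.33 on the log2 scale, the disulfide isomerase PDIA4 by 1.24 and HSPA5, the main ER HSP70, by 1.06.

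The 49 ribosomal protein mRNAs had a median of -0.76 in HuCCT1 (camera adjusted p = 6.1e-28; adjusted p = 0.20 with an estimated correlation), and RPL3 went from 2020.4 ± 36.9 to 921 ± 73.7 CPM. The median was -0.68 without CB-5339 replicate 1, the library apart on the second component. The summed share of counts on ribosomal protein genes fell from 6.14 ± 0.14% (SD, n = 4) to 3.72 ± 0.41% (SD, n = 3). Markers of cell types were mixed. Of 19 cholangiocyte markers 5 rose, 10 fell and 4 did not pass (median -0.33, camera adjusted p = 0.0050; adjusted p = 0.40 with an estimated correlation), with the transcription factor SOX9 at 2.09 and the chloride channel CFTR at -2.57. That call was lost with limma-voom (adjusted p = 0.13). Of 6 fibroblast markers 1 rose and 5 fell (median -1.39, camera adjusted p = 7.5e-05; adjusted p = 0.096 with an estimated correlation), led by the complement proteases C1R at -2.42 and C1S at -1.89. Without CB-5339 replicate 1 the fibroblast median was -1.12, and with no low-count filter it was 0.18, so the direction of that median is not settled. Of 5 endothelial markers 4 rose and 1 did not pass (median 1.57, camera adjusted p = 0.055), and the list passed with limma-voom (adjusted p = 0.045), no low-count filter (0.0036), the 1 CPM filter (0.029) and without CB-5339 replicate 2 (0.016). Only 2 hepatocyte and 2 leukocyte markers were measured, too few for a test.

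The remaining lists did not pass in HuCCT1, although members of each changed. Of 24 ATF4 and PERK targets 8 rose, 7 fell and 9 did not pass (median 0.06, camera adjusted p = 0.97), with the mTORC1 inhibitor DDIT4 at -2.69, ATF4 at -0.78 and ATF3 at 2.55. Of 27 ER-associated degradation genes 4 rose, 10 fell and 13 did not pass (median -0.14, adjusted p = 0.22), and of 27 genes for VCP and its cofactors 7 rose, 10 fell and 10 did not pass (median -0.03, adjusted p = 0.47). Of 26 NRF2 and oxidative stress genes 14 rose, 4 fell and 8 did not pass, with 15 and 4 adjusted over the list alone (median 0.40, adjusted p = 0.055), including the glutamate-cysteine ligase subunit GCLM at 1.68. Of 41 G2/M and mitosis genes 21 rose, 6 fell and 14 did not pass, with 22 and 7 adjusted over the list alone (median 0.28, adjusted p = 0.055), with the checkpoint protein MAD2L1 at 1.01 and the kinesin KIF20A at -0.97. Of 36 autophagy and lysosome genes 17 rose, 9 fell and 10 did not pass (median 0.14, adjusted p = 0.12), with the autophagy receptor SQSTM1 at 1.59. Of 26 p53 targets 11 rose, 5 fell and 10 did not pass (median 0.08, adjusted p = 0.091), including the cyclin-dependent kinase inhibitor CDKN1A at 1.88. Of 29 apoptosis regulators 11 rose, 4 fell and 14 did not pass, with 10 and 3 adjusted over the list alone (median -0.01, adjusted p = 0.20). Of 25 amino acid synthesis and tRNA synthetase genes 5 rose, 8 fell and 12 did not pass (median -0.08, adjusted p = 0.62), and of 25 cholesterol synthesis and uptake genes likewise 5 rose, 8 fell and 12 did not pass (median -0.09, adjusted p = 0.47).

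Of 21 fatty acid and lipid synthesis genes in HuCCT1 8 rose, 7 fell and 6 did not pass (median 0.11, adjusted p = 0.88), with the desaturase SCD at -1.74. Of 23 antigen presentation genes 7 rose, 10 fell and 6 did not pass, with 8 and 10 adjusted over the list alone (median -0.10, adjusted p = 0.30). Of 20 mesenchymal and matrix genes 9 rose, 7 fell and 4 did not pass (median 0.15, adjusted p = 0.30), with the growth factor TGFB2 at -2.07. Of 29 epithelial junction genes 9 rose, 11 fell and 9 did not pass (median 0.05, adjusted p = 0.91). Of 33 glycolysis and hypoxia genes 13 rose, 11 fell and 9 did not pass, with 14 and 11 adjusted over the list alone (median 0.05, adjusted p = 0.23). Of 39 nuclear oxidative phosphorylation genes 10 rose, 8 fell and 21 did not pass (median 0.09, adjusted p = 0.82), and of 13 mitochondrially encoded mRNAs 1 rose, 4 fell and 8 did not pass (median -0.14, adjusted p = 0.22). With no low-count filter the ER-associated degradation (adjusted p = 0.024), p53 (0.010) and mitochondrial lists (0.0089) passed, and with thinned counts the mesenchymal list (0.035). The median, mean and test differed in sign for the apoptosis, mesenchymal and epithelial lists. Other scalings turned the sign of the amino acid, apoptosis and VCP cofactor medians.

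Across HuCCT1, 13411 genes were tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, and 3744 rose and 3573 fell, 807 and 876 of them at least 2-fold. The CPM of the groups did not overlap for 7194 of the tested genes, 53.6%, where chance gives 5.71%. Against a 1.5-fold change, 1006 genes rose and 956 fell. Without CB-5339 replicate 1, 3499 rose and 3374 fell. Camera called 14 of 32 lists, and the interferon and senescence lists were the 2 that held with an estimated correlation.

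**Figure D2:**
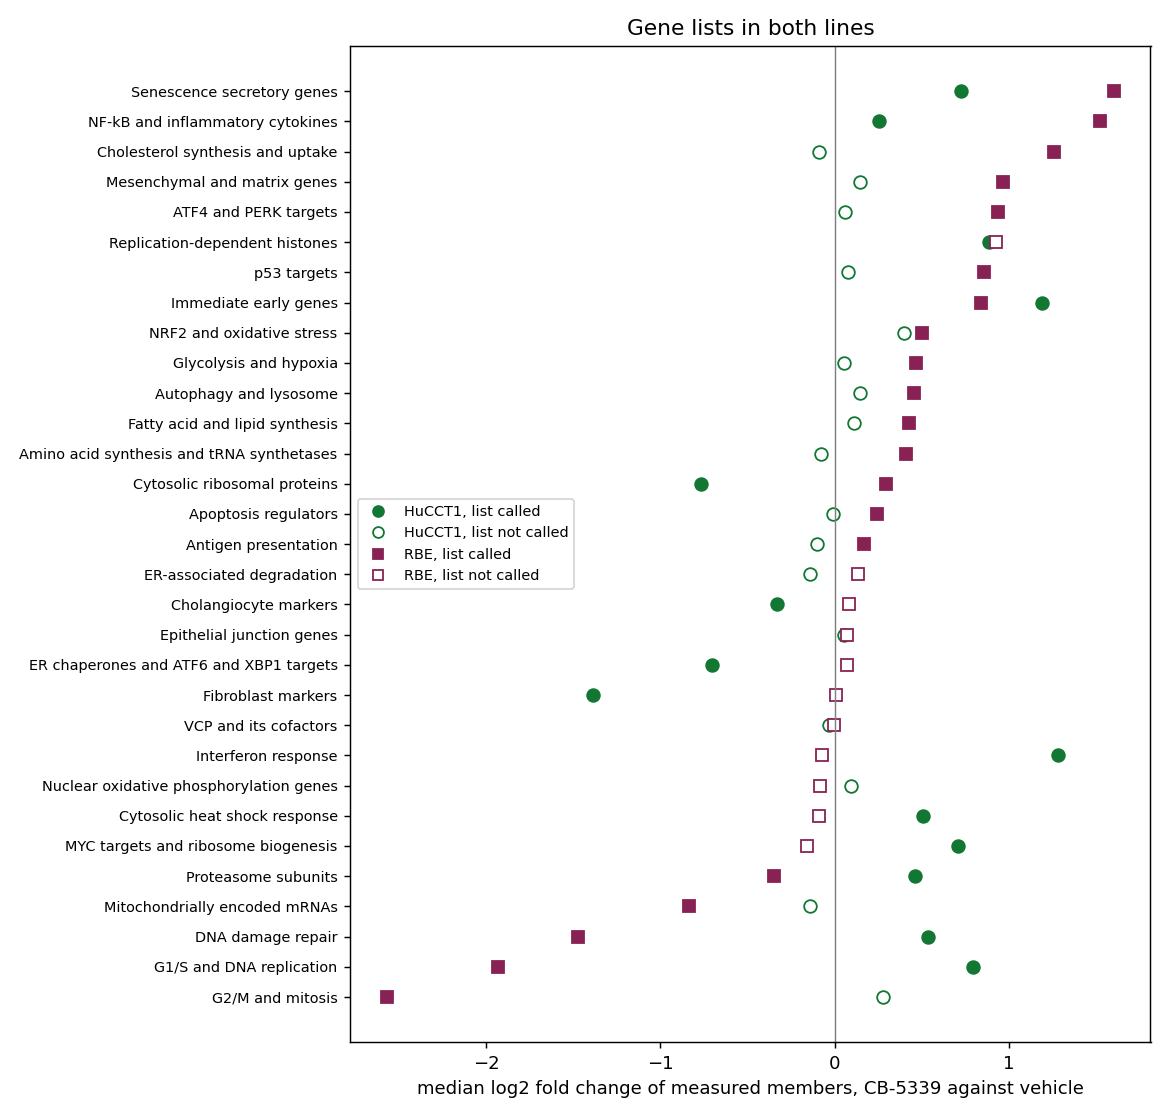
Median log2 fold change (x axis, CB-5339 over vehicle) of the 31 gene lists tested in both lines (y axis), with a colour per line and filled points for lists called by camera at its preset correlation. G1/S genes lie at 0.79 in HuCCT1 and -1.93 in RBE, and ribosomal protein mRNAs at -0.76 in HuCCT1 and 0.30 in RBE.

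In RBE, CB-5339 lowered cell cycle genes as a block and raised p53 targets, inflammatory and senescence-associated genes, matrix genes, and cholesterol synthesis genes. The cholesterol call was lost with an estimated correlation (adjusted p = 0.28), and the calls of the other lists held. All 41 G2/M genes fell, and 44 of 45 G1/S genes fell. FAM111B (ENSG00000189057, chromosome 11, 59107185 to 59127410), a trypsin-like protease, went from 47.8 ± 3.58 to 2.66 ± 1.18 CPM (log2 -4.17, SE 0.18). GDF15 (ENSG00000130513, chromosome 19, 18374731 to 18389176), a stress-induced cytokine, rose from 72.2 ± 7.56 to 1049 ± 359 CPM (log2 3.86, SE 0.13).

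INHBA, the subunit of activin A, rose in RBE by 4.34 on the log2 scale (SE 0.12), from 5.35 ± 1.52 to 109 ± 2.74 CPM. The long non-coding RNA LINC02154 rose by 4.68 (SE 0.25), the autophagy gene ATG9B by 3.86 (SE 0.23) and the phospholipase PLA1A by 3.57 (SE 0.22). TCN1, a vitamin B12 carrier, rose by 3.42 (SE 0.15), and PADI2, which converts arginine to citrulline in proteins, by 3.17 (SE 0.16). INSIG1, which retains the cholesterol-sensing SREBP complex in the ER, rose by 3.81 (SE 0.28), and by 3.05 without CB-5339 replicate 3. Among the other large falls, the helicase PIF1 changed by -3.94 (SE 0.24), the kinetochore protein SPC25 by -3.88 (SE 0.26) and the condensin subunit NCAPG by -3.85 (SE 0.13). The exonuclease EXO1 changed by -3.70 (SE 0.15), the DNA glycosylase NEIL3 by -3.68 (SE 0.28), the cohesin acetyltransferase ESCO2 by -3.64 (SE 0.20) and the replication initiation factor MCM10 by -3.58 (SE 0.17). INHBA, GDF15, SPC25, NCAPG and ESCO2 overlap other measured genes, so reads there are uncertain by gene.

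The G2/M list had a median of -2.57 in RBE (camera adjusted p = 1.4e-94; adjusted p = 0.0059 with an estimated correlation). The proliferation marker MKI67 changed by -3.41 (SE 0.11), the motor protein KIF11 by -2.95, the centromere protein CENPF by -2.83 and topoisomerase TOP2A by -2.58. The G1/S list, with 44 falls and 1 gene not passing, had a median of -1.93 (camera adjusted p = 6.4e-53; adjusted p = 0.0086 with an estimated correlation), with UHRF1, a cofactor of maintenance DNA methylation, at -3.54 and RRM2 at -3.14. Of 34 DNA damage repair genes 1 rose, 29 fell and 4 did not pass (median -1.48, camera adjusted p = 1.2e-22; adjusted p = 0.018 with an estimated correlation), with BRCA1 at -2.65 and CLSPN at -3.49. The medians were -2.53, -1.85 and -1.56 without CB-5339 replicate 3. Of 28 p53 targets 24 rose and 4 did not pass (median 0.86, camera adjusted p = 1.0e-18; adjusted p = 0.029 with an estimated correlation). CDKN1A rose by 2.47 (SE 0.08), from 185 ± 9.56 to 1029 ± 137 CPM, the ribonucleotide reductase subunit RRM2B by 1.82 and the RNA-binding protein ZMAT3 by 1.61.

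The senescence secretory, NF-kB and matrix lists rose in RBE and held with an estimated correlation. Of 16 senescence secretory genes 11 rose, 2 fell and 3 did not pass (median 1.60, camera adjusted p = 9.8e-12; adjusted p = 0.031 with an estimated correlation), and LMNB1, a lamin lost in senescent cells, changed by -2.97. Of 17 NF-kB and cytokine genes 14 rose, 1 fell and 2 did not pass, with 14 and 2 adjusted over the list alone (median 1.53, camera adjusted p = 7.7e-09; adjusted p = 0.011 with an estimated correlation). IL1B rose by 3.01, the macrophage growth factor CSF1 by 1.57 and LIF by 1.28. Of 25 mesenchymal and matrix genes 21 rose, 1 fell and 3 did not pass (median 0.96, camera adjusted p = 2.4e-19; adjusted p = 0.010 with an estimated correlation), with CCN2, a matricellular protein, at 2.49 and TGFB2 at 1.44. Of 25 immediate early genes 20 rose, 4 fell and 1 did not pass (median 0.84, camera adjusted p = 1.7e-06; adjusted p = 0.18 with an estimated correlation).

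Of 24 cholesterol synthesis and uptake genes in RBE 21 rose, 1 fell and 2 did not pass (median 1.26, camera adjusted p = 2.1e-10; adjusted p = 0.28 with an estimated correlation). The sterol methyl oxidase MSMO1 rose by 2.93, the reductase DHCR7 by 1.94 and the transcription factor SREBF2 by 1.51. Replicate 3, which stood apart on the second component, widened the spread: with CB-5339, MSMO1 was at 316 ± 157 CPM (SD, n = 3), and without replicate 3 the list median was 0.99. Of 23 fatty acid genes 14 rose, 2 fell and 7 did not pass (median 0.43, camera adjusted p = 0.0027; adjusted p = 0.41 with an estimated correlation), with SCD at 2.32 and the lipid droplet protein PLIN2 at 1.26. Of 25 ATF4 and PERK targets 21 rose, 2 fell and 2 did not pass (median 0.94, camera adjusted p = 3.1e-08; adjusted p = 0.24 with an estimated correlation), with DDIT3, known as CHOP, at 2.82 and ATF3 at 2.81. DDIT3, with 1056 counts over the 14 libraries, overlaps MARS1 (10496 counts) and MBD6 (3206 counts) on the opposite strand. The strand used in counting is unknown, so the DDIT3 value is uncertain. The ATF4 median was 0.76 without CB-5339 replicate 3. Of 25 amino acid and tRNA synthetase genes 13 rose, 3 fell and 9 did not pass (median 0.41, camera adjusted p = 0.0027; adjusted p = 0.35 with an estimated correlation), with the synthetases AARS1 at 1.35 and CARS1 at 1.20.

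Of 37 autophagy and lysosome genes in RBE 25 rose, 4 fell and 8 did not pass (median 0.45, camera adjusted p = 6.0e-07; adjusted p = 0.18 with an estimated correlation), with the lysosomal cholesterol transporter NPC1 at 1.49 and the protease CTSB at 1.38. Of 29 NRF2 genes 20 rose, 2 fell and 7 did not pass (median 0.50, camera adjusted p = 1.7e-06; adjusted p = 0.14 with an estimated correlation), with the aldo-keto reductase AKR1C1 at 2.27. Of 32 glycolysis and hypoxia genes 18 rose, 9 fell and 5 did not pass (median 0.47, camera adjusted p = 0.0072; adjusted p = 0.38 with an estimated correlation). Of 20 antigen presentation genes 9 rose, 4 fell and 7 did not pass (median 0.17, camera adjusted p = 0.022; adjusted p = 0.28 with an estimated correlation), with HLA-B at 1.75 and HLA-E at 1.22. Of 28 apoptosis regulators 16 rose, 5 fell and 7 did not pass (median 0.25, camera adjusted p = 0.024; adjusted p = 0.14 with an estimated correlation), with both BIRC3, an inhibitor of apoptosis, at 1.66 and the pro-apoptotic BBC3 at 1.44. The antigen call was lost with limma-voom (adjusted p = 0.054) and at the margin with thinned counts (adjusted p = 0.0504), which also ended the glycolysis call (adjusted p = 0.063). Of 49 ribosomal protein mRNAs 38 rose and 11 did not pass, or 40 rose adjusted over the list alone (median 0.30, camera adjusted p = 8.4e-05; adjusted p = 0.51 with an estimated correlation), with RPL12 at 0.68. Of 33 proteasome subunits 23 fell and 10 did not pass, or 24 fell adjusted over the list alone (median -0.35, camera adjusted p = 5.6e-05; adjusted p = 0.28 with an estimated correlation), with PSMC3 at -1.15.

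All 13 mitochondrially encoded mRNAs fell in RBE (median -0.84, camera adjusted p = 2.1e-07; adjusted p = 0.28 with an estimated correlation), while the mitochondrial ribosomal RNAs did not fall. MT-CYB changed by -1.68, MT-ATP8 by -1.45, MT-CO3 by -1.28 and MT-CO1 by -0.31. The small rRNA MT-RNR1 rose by 0.91 (SE 0.08, edgeR adjusted p = 9.3e-11), and the large rRNA MT-RNR2 was at 0.09 (SE 0.09, edgeR adjusted p = 0.38). In HuCCT1 the large rRNA MT-RNR2 fell by 0.38 on the log2 scale (edgeR adjusted p = 0.00051), MT-CYB fell by 0.76 and MT-CO3 by 0.64, and MT-ND2 rose by 0.38. The share of all counts on mitochondrial transcripts went from 11.9 ± 1.19% (SD, n = 4) to 8.48 ± 1.03% (SD, n = 3) in RBE and from 5.98 ± 0.40% to 5.59 ± 0.15% in HuCCT1. It was lowest among the RBE CB-5339 libraries in replicate 3, at 7.31%, and without that library the RBE median was -0.73.

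**Figure D3:**
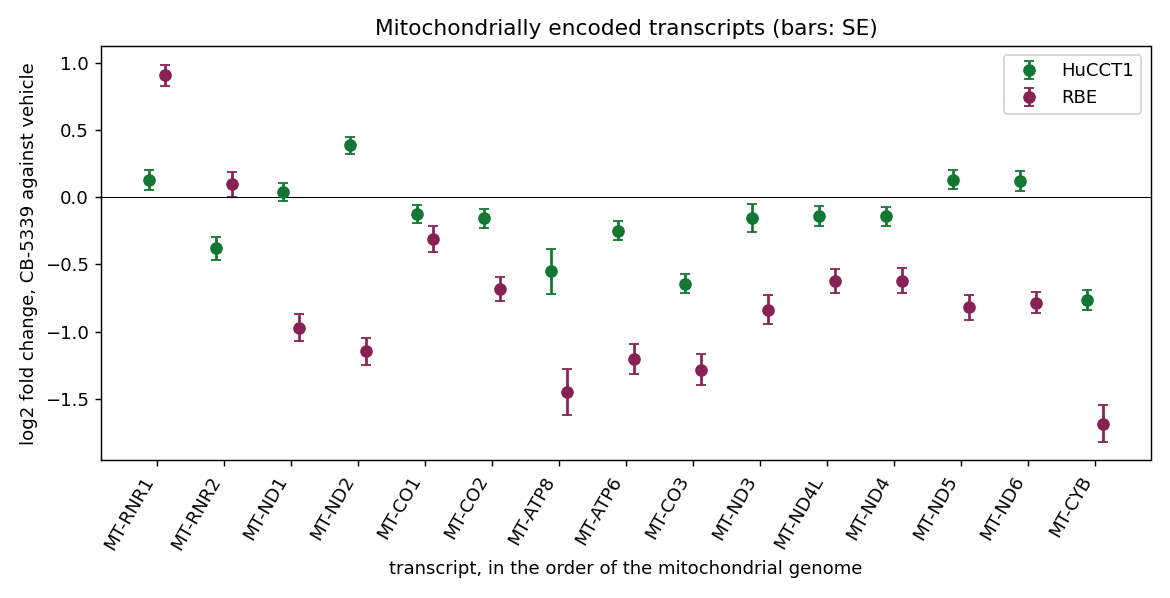
Log2 fold change with CB-5339 (y axis, bars 1 SE) of the mitochondrial rRNAs MT-RNR1 and MT-RNR2 and the 13 mitochondrially encoded mRNAs, in genome order (x axis), for each line. In RBE the mRNAs all lie below 0, from -0.31 for MT-CO1 to -1.68 for MT-CYB, and MT-RNR1 lies at 0.91.

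The other lists did not pass in RBE. Of 27 ER chaperones 7 rose, 10 fell and 10 did not pass (median 0.07, camera adjusted p = 0.83), with the HSP40 co-chaperone DNAJB9 at 1.29 and calreticulin CALR at -0.60. Of 27 ER-associated degradation genes 11 rose, 7 fell and 9 did not pass (median 0.14, adjusted p = 0.35), with ERLEC1, an ER lectin, at 0.89. Of 27 genes for VCP and its cofactors 6 rose, 10 fell and 11 did not pass (median -0.003, adjusted p = 0.83), with UFD1, the partner of NPLOC4, at -0.64. Of 25 heat shock genes 8 rose, 8 fell and 9 did not pass (median -0.09, adjusted p = 0.83), with DNAJB2 at 1.48 and DNAJA1 at -1.02. Of 27 interferon genes 7 rose, 9 fell and 11 did not pass (median -0.07, adjusted p = 0.92), with OAS3 at -1.36 and the guanylate-binding protein GBP2 at 0.90. Of 34 MYC targets 5 rose, 16 fell and 13 did not pass (median -0.16, adjusted p = 0.067), with MYC at 1.03 and the snoRNP protein NOP56 at -0.98. Of 39 nuclear oxidative phosphorylation genes 7 rose, 7 fell and 25 did not pass (median -0.08, adjusted p = 0.72). Of 5 histone genes 3 rose, 1 fell and 1 did not pass (median 0.93, adjusted p = 0.83), among them H2BC21 at 1.00, a call lost without vehicle replicate 2 (edgeR adjusted p = 0.066), vehicle replicate 3 (0.061) or CB-5339 replicate 3 (0.21).

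Cell type marker lists gave no call in RBE in the reported analysis. Of 20 epithelial junction genes 5 rose, 6 fell and 9 did not pass (median 0.07, camera adjusted p = 0.92), with E-cadherin CDH1 at -0.88 and desmoglein DSG2 at 0.99. Of 19 cholangiocyte markers 7 rose, 5 fell and 7 did not pass (median 0.08, adjusted p = 0.056), with osteopontin SPP1 at 2.25 and the water channel AQP1 at 2.32. The cholangiocyte list passed with DESeq2 (adjusted p = 0.031) and without vehicle replicate 3 (0.045), CB-5339 replicate 1 (0.048) or CB-5339 replicate 3 (0.046). Its medians in those fits were 0.091, 0.0012, 0.19 and 0.031 in the same order, so in some it passed with a median near 0. Of 9 hepatocyte markers 4 rose, 3 fell and 2 did not pass (median 0.08, adjusted p = 0.92), and of 9 fibroblast markers 4 rose, 3 fell and 2 did not pass (median 0.01, adjusted p = 0.16), with the collagen COL6A3 at 2.75. Only 4 endothelial markers were measured and no leukocyte marker passed the count filter, too few for a test. The median, mean and test differed in sign for the ER chaperone, heat shock, interferon, epithelial and hepatocyte lists, and other scalings turned the sign of the fibroblast and VCP cofactor medians. Across RBE, 13970 genes were tested with edgeR's quasi-likelihood test, and 4134 rose and 4125 fell, 1090 and 1107 of them at least 2-fold. The CPM of the groups did not overlap for 8147 genes, 58.3%. Against a 1.5-fold change 1366 rose and 1290 fell. Without CB-5339 replicate 3, 3882 rose and 3885 fell. Camera called 20 of 32 lists, and 7 held with an estimated correlation.

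Single genes rose or fell in both lines. DUSP5 rose by 3.86 in HuCCT1 and 3.08 in RBE, the cytokine IL1B by 2.93 and 3.01, the stress transcription factor ATF3 by 2.55 and 2.81, and the growth arrest gene GADD45A by 1.89 and 2.63. The scaffold AKAP12 rose by 2.34 and 2.27, HES4 by 1.94 and 2.33, the laminin subunit LAMB3 by 1.92 and 1.95 and the protease inhibitor SERPINB7 by 1.91 and 2.06. Genes that fell in both lines included ATOH8, at -4.74 and -2.46, and ID2 and ID3, inhibitors of basic helix-loop-helix transcription factors, at -1.98 and -1.51 and at -1.32 and -1.24. The Wnt receptor FZD2 was at -1.30 and -1.29, the iron regulator HFE at -1.33 and -1.77 and CLDN2 at -5.48 and -1.33. FLRT3, an adhesion protein, was at -2.77 and -1.23, and in RBE its call was lost with thinned counts (log2 -0.99, edgeR adjusted p = 0.098). RN7SL1, the RNA of the signal recognition particle, was at -1.82 and -1.95, which is uncertain because the genome holds many copies of it.

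Across the 12098 genes tested in both lines, Pearson's r of the fold changes was -0.0029 (jackknife SE over libraries 0.0248) and Spearman's rho was -0.038. This correlation is across genes, which are not independent replicates, and r was 0.0927 without a low-count filter. Of 4233 genes called in both lines, 1050 rose in both where independent lists give 994, and 909 fell in both where they give 1003. A further 1204 rose in HuCCT1 and fell in RBE, where independent lists give 1057, and 1070 fell in HuCCT1 and rose in RBE, against 943. Thus 46.3% had the same direction. The lines share no control libraries. Camera called 7 of 31 lists in both lines, 3 in the same direction (immediate early, senescence and NF-kB genes) and 4 in opposite directions (G1/S, DNA repair, proteasome and ribosomal protein genes). With an estimated correlation, senescence alone of these 7 lists held in both lines (camera adjusted p = 0.027 in HuCCT1 and 0.031 in RBE). In HuCCT1 that adjusted p was 0.096 for immediate early and G1/S genes, 0.22 for NF-kB, 0.20 for DNA repair and ribosomal proteins and 0.30 for the proteasome. The senescence list shares cytokine genes with the NF-kB list, so their calls are not independent.

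**Figure D4:**
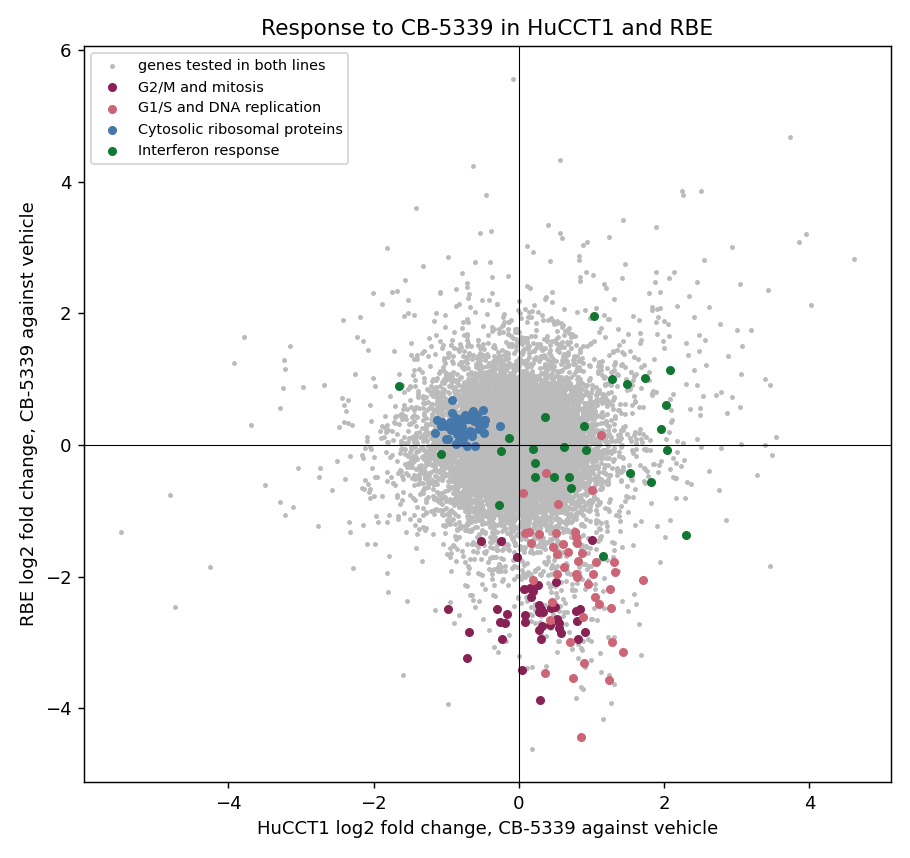
Log2 fold change with CB-5339 in HuCCT1 (x axis) against RBE (y axis) for the 12098 genes tested in both lines (grey), with G2/M, G1/S, ribosomal protein and interferon genes coloured. The cloud has no evident slope (r = -0.0029), G1/S genes lie right of and below 0 (medians 0.79 and -1.93), and ribosomal protein genes lie left of 0 and mostly above it (medians -0.76 and 0.30).

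The difference between the responses, RBE minus HuCCT1, was tested over all 14 libraries. All 45 G1/S genes were lower (median -2.72, camera adjusted p = 1.1e-79; adjusted p = 0.0013 with an estimated correlation), and so were all 41 G2/M genes (median -2.76, camera adjusted p = 2.2e-82; adjusted p = 0.0026 with an estimated correlation). RRM2 differed by -4.54, UHRF1 by -4.26 and CDC6 by -4.25. All 49 ribosomal protein mRNAs were higher (median 1.09, camera adjusted p = 1.0e-29; adjusted p = 0.14 with an estimated correlation).

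Among repair genes 1 was higher, 29 were lower and 4 did not pass (median -1.90, camera adjusted p = 3.6e-31; adjusted p = 0.0027 with an estimated correlation), with CLSPN at -4.70. Of 34 MYC targets 27 were lower and 7 did not pass (median -0.96, camera adjusted p = 7.5e-11; adjusted p = 0.044 with an estimated correlation). Of 33 proteasome subunits 1 was higher, 28 were lower and 4 did not pass (median -0.88, camera adjusted p = 3.8e-11; adjusted p = 0.17 with an estimated correlation). Of 25 heat shock genes 2 were higher, 14 lower and 9 did not pass (median -0.44, camera adjusted p = 0.00035; adjusted p = 0.20 with an estimated correlation). Of 39 interferon genes 3 were higher, 19 lower and 17 did not pass (median -0.76, or -0.68 over the 27 members tested in both lines; camera adjusted p = 0.0078; adjusted p = 0.24 with an estimated correlation), with OAS3 at -3.64. Of 13 mitochondrial mRNAs 12 were lower and 1 did not pass (median -0.87, camera adjusted p = 0.00023; adjusted p = 0.35 with an estimated correlation), and the median was -0.65 without RBE CB-5339 replicate 3.

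Mesenchymal and matrix genes responded more in RBE: 14 were higher, 4 lower and 7 did not pass (median 1.01, or 1.29 over the 20 members tested in both lines; camera adjusted p = 3.0e-09; adjusted p = 0.0097 with an estimated correlation), with TGFB2 at 3.54 and INHBA at 3.80. Of 33 NF-kB genes 15 were higher, 4 lower and 14 did not pass (median 0.77, or 1.05 over the 16 members tested in both; camera adjusted p = 0.0012; adjusted p = 0.034 with an estimated correlation). Of 25 cholesterol genes 21 were higher and 4 did not pass, with 21 higher and 1 lower adjusted over the list alone (median 1.24, camera adjusted p = 3.0e-09; adjusted p = 0.20 with an estimated correlation). The cholesterol median was 0.90 without RBE CB-5339 replicate 3. Of 25 ATF4 targets 16 were higher, 1 lower and 8 did not pass, with 17 and 1 adjusted over the list alone (median 0.99, camera adjusted p = 1.9e-05; adjusted p = 0.26 with an estimated correlation), with DDIT4 at 3.62. Of 27 ER chaperones 16 were higher, 1 lower and 10 did not pass, with 17 and 1 adjusted over the list alone (median 0.58, camera adjusted p = 3.7e-05; adjusted p = 0.20 with an estimated correlation), with HSPA5 at 1.31. Of 28 p53 targets 18 were higher, 2 lower and 8 did not pass (median 0.77, camera adjusted p = 0.00023; adjusted p = 0.15 with an estimated correlation). Of 37 autophagy genes 18 were higher, 8 lower and 11 did not pass (median 0.25, camera adjusted p = 0.0067; adjusted p = 0.20 with an estimated correlation). Of 27 amino acid genes 15 were higher, 3 lower and 9 did not pass (median 0.42, camera adjusted p = 0.014; adjusted p = 0.56 with an estimated correlation). Of 23 antigen presentation genes 10 were higher, 4 lower and 9 did not pass (median 0.53, or 0.33 over the 20 members tested in both; camera adjusted p = 0.046; adjusted p = 0.24 with an estimated correlation). That antigen call was lost without HuCCT1 vehicle replicate 4 (adjusted p = 0.056), HuCCT1 CB-5339 replicate 1 (0.062), RBE vehicle replicate 1 (0.059) or 3 (0.061), or RBE CB-5339 replicate 3 (0.062), with library totals (0.051) and with thinned counts (0.067).

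The difference did not pass for ER-associated degradation (camera adjusted p = 0.070), fibroblast (0.070), senescence (0.087), fatty acid (0.11), hepatocyte (0.18), immediate early (0.18), NRF2 (0.21), glycolysis (0.32), cholangiocyte (0.33), endothelial (0.35), apoptosis (0.37), histone (0.40), epithelial (0.62), VCP cofactor (0.62) and nuclear oxidative phosphorylation genes (0.64). The ER-associated degradation list passed with no low-count filter (adjusted p = 0.0036), the 1 CPM filter (0.043), GC and length trends removed (0.043) and without RBE vehicle replicate 4 (0.044), and the fibroblast list with library totals (0.043) and without HuCCT1 CB-5339 replicate 1 (0.045). The senescence list passed with no low-count filter (0.034) and thinned counts (0.032), NRF2 genes with no low-count filter (0.049) and fatty acid genes without RBE CB-5339 replicate 2 (0.032). With 3 members measured, leukocyte markers were not tested. The median, mean and test differed in sign for the epithelial, oxidative phosphorylation and senescence lists. Other scalings turned the sign of the apoptosis, fatty acid, oxidative phosphorylation and VCP cofactor medians.

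The single genes with the largest differences were of 2 kinds. Some were well counted in both lines: FAM111B was 2.25-fold higher with CB-5339 in HuCCT1 and 18.1-fold lower in RBE (log2 difference -5.29, SE 0.22), ESCO2 2.46-fold higher and 12.6-fold lower (-4.91, SE 0.25) and the cell cycle kinase PKMYT1 3.18-fold higher and 9.13-fold lower (-4.84, SE 0.28). The other genes were near 0 counts in a group of one line, so their fitted differences are no bounds. MUC5AC (7.33, SE 0.73) was 17.8-fold lower in HuCCT1 and had 3 counts with vehicle and 20 with CB-5339 in RBE, a ratio of 10.7 with a counting interval of 3.17 to 56.1. Its value was 8.25 without RBE vehicle replicate 4 and 6.64 without RBE CB-5339 replicate 3, and with thinned counts it was 3.78 (edgeR adjusted p = 0.21). PTPRR, a tyrosine phosphatase (4.88, SE 0.59), went from 6 to 77 counts in RBE, and ASS1, argininosuccinate synthase (4.82, SE 0.39), from 9 to 47 counts in RBE and from 2233 to 343 in HuCCT1. WNT10A (4.77, SE 1.33) and the sugar transporter SLC2A10 (4.71, SE 1.33) had 0 counts with vehicle and 4 with CB-5339 in RBE, at least 2.14-fold higher against a floor of 3 counts over the group, and both fell in HuCCT1, from 733 to 172 and from 1384 to 335 counts. With thinned counts the SLC2A10 difference did not pass (edgeR adjusted p = 0.20).

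PLAC8 (4.88, SE 1.57, edgeR adjusted p = 0.0092) had 0 and 3 counts in RBE, too few for a fold, and fell from 589 to 100 counts in HuCCT1. Its call was lost without RBE CB-5339 replicate 2 (edgeR adjusted p = 0.10) and with thinned counts (0.16). CCDC198 (-5.63, SE 1.19) had 0 and 10 counts in HuCCT1, at least 6.17-fold higher, and was 1.31-fold lower in RBE. EFR3B, a membrane scaffold (-4.90, SE 0.63), had 3 and 27 counts in HuCCT1, a ratio of 16.7 with an interval of 5.13 to 85.8, and its difference was -7.71 without HuCCT1 vehicle replicate 3. RPE65, the retinoid isomerohydrolase (-4.87, SE 1.37), had 9 and 0 counts in RBE, at least 1.87-fold lower, and its difference was -3.77 without RBE vehicle replicate 2. With thinned counts RPE65 did not pass (edgeR adjusted p = 0.055). Floors and intervals cover counting error only. Across 15371 genes tested with edgeR's quasi-likelihood test, the response was higher in RBE for 3821 and lower for 3799, 1864 and 1716 of them by at least 2-fold. These counts were 3651 and 3715 without HuCCT1 CB-5339 replicate 1, and 3724 and 3537 without RBE CB-5339 replicate 3. Camera called 18 of 33 lists and 6 held with an estimated correlation.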

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

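The tests of mislabelling, scaling, GC content and length, single libraries and mitochondrial rRNAs in this part were chosen only after the results were seen, while the matched-gene comparison and the regroupings of libraries were set up before their values were known.

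The response to CB-5339 differed between the lines for a large share of genes: it was higher in RBE for 3821 genes and lower for 3799. Of 60 drawn regroupings within the lines, 1, the real one, reached 7620 genes and the highest other gave 4592. Regrouping mixes treated and vehicle libraries within a line. With 3 treated and 4 vehicle libraries, no other split is even for treatment. The treatment effect is thus diluted and partly moved into the spread within groups, but not removed. The regrouping argues against a count this large without any treatment effect and cannot test whether the lines respond alike. The drawn regroupings with any other gene called, 2 in number, kept the real groups of 1 line, and edgeR called 0 genes in each of the 57 draws that regrouped both lines. Within the lines, 1 of 35 splits, the real one, reached 7317 genes in HuCCT1 and 1 of 35 reached 8259 in RBE. The highest other split of each gave 0 genes in edgeR. Chance is argued against there, although 1 of 35 is the smallest share these splits can give. For the 1959 genes called in both lines in one direction the splits say nothing (1 of 35 reached it, with 0 in the highest other), because no other RBE split called a gene in edgeR, and independent lists give 994 higher and 1003 lower in both. The numbers of called lists cannot be judged by these splits, which stay uneven for treatment and still carry part of its contrast. In HuCCT1, 8 of 35 splits gave at least the 14 lists called (highest other 16). For RBE 2 of 35 gave at least the 20 lists (highest other 21), and for the difference 14 of 60 gave at least the 18 lists (highest other 21). These list counts neither exclude chance nor point to it. For the correlation between lines the splits say nothing, because nearly any split lies at least as far from 0 as a value this small. Of 35 splits 34 lay at least as far from 0 as 0.0029, the highest other at 0.114.

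Lists whose response differed between the lines, as median log2 difference, were G1/S at -2.72, G2/M at -2.76, DNA repair at -1.90, MYC targets at -0.96, proteasome at -0.88, mitochondrially encoded mRNAs at -0.87, interferon genes at -0.76 and heat shock genes at -0.44. On the other side were cholesterol genes at 1.24, ribosomal proteins at 1.09, mesenchymal genes at 1.01, ATF4 targets at 0.99, p53 targets at 0.77, NF-kB genes at 0.77, ER chaperones at 0.58, antigen presentation at 0.53, amino acid genes at 0.42 and autophagy genes at 0.25. With an estimated correlation the calls held for G1/S, G2/M, DNA repair, MYC, mesenchymal and NF-kB genes and were lost for the other 12: adjusted p = 0.14 for ribosomal proteins, 0.15 for p53, 0.17 for the proteasome, 0.20 for heat shock, cholesterol, ER chaperone and autophagy genes, 0.24 for interferon and antigen genes, 0.26 for ATF4, 0.35 for mitochondrial mRNAs and 0.56 for amino acid genes. Among genes, VCP differed by -0.79, MUC5AC by 7.33, PTPRR by 4.88, PLAC8 by 4.88, ASS1 by 4.82, WNT10A by 4.77 and SLC2A10 by 4.71. CCDC198 differed by -5.63, FAM111B by -5.29, ESCO2 by -4.91, EFR3B by -4.90, RPE65 by -4.87 and PKMYT1 by -4.84.

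G1/S genes were higher with CB-5339 in HuCCT1 and lower in RBE. A single mislabelled library is argued against, since 0 libraries had a mean G1/S level inside the range of the other group: mean log2 CPM ran from 5.25 to 5.37 with vehicle and from 6.03 to 6.08 with CB-5339 in HuCCT1, and from 5.67 to 5.73 and from 3.62 to 3.82 in RBE. The choice among the scalings run is argued against, since the lowest HuCCT1 list median over the others was 0.78. All of these scalings work on relative counts, so a change in total mRNA per cell could not show in them. An exchange of the vehicle and CB-5339 labels of one whole line cannot be told apart from a real difference, because the correlation between lines as labelled, -0.0029, would stay as small with its sign turned. A biological difference between the lines in how they respond to VCP inhibition also stays open, as a hypothesis that was not tested further.

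All 49 ribosomal protein mRNAs were lower with CB-5339 in HuCCT1, with a median of -0.76 (adjusted p = 0.20 with an estimated correlation). Trends on GC content and on the length of the longest annotated transcript are argued against as the whole cause, since the median was -0.82 with them removed. So is the choice among the scalings run, since the highest median over the others was -0.68, though a change in total mRNA per cell could not show in them. A loss of short abundant mRNAs in general needs a fall of matched genes near that of the list. The 120 genes matched on level, annotated length and GC content had a median of -0.12 (SE 0.077), so as a set they did not share the fall. Lengths were those of the longest annotated transcript, which need not be the expressed one, so a loss of short mRNAs cannot be decided. The bound written for this comparison was reworded after its value was seen, the value clears the stricter bound by only about its SE, the matched genes spread from -0.62 to 0.17 between quartiles, and they were longer than the list (medians 2407 and 1872 bases). A lowered level of ribosomal protein mRNAs in these cultures may be biological, as a hypothesis found and tested on the same data, and read loss in the authors' counting was not tested.

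All 13 mitochondrially encoded mRNAs were lower with CB-5339 in RBE (adjusted p = 0.28 with an estimated correlation). Fewer mitochondrial transcripts of every kind are argued against, since the lower of the rRNA changes was 0.094, although the depletion of rRNA or selection of poly(A) RNA in the library kit is unknown and could act on rRNAs alone. A single CB-5339 library is argued against, since the highest median over the fits without 1 CB-5339 library was -0.73. With totals and TMM factors from nuclear genes alone the median was -0.84 (SE over members 0.133). It was -0.92 with totals of nuclear genes without TMM factors (SE 0.132). The mitochondrial share was a small part of the totals and fell, from 11.9% to 8.48%. Leaving it out of the totals could therefore hardly have raised the median, so these scalings are no separate evidence. A change in mitochondrial mRNA level or stability with CB-5339 may be biological, as a hypothesis, and was not tested further.

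Groups of 4 vehicle libraries were taken for each named gene and line, and for measures of the libraries such as total counts. Among these 306 groups, 22 held a library far from the other 3, where chance gives about 15.3. The ratios of gap to range follow with no explanation, for 21 of them. In HuCCT1 vehicle the ratio was 0.868 for SERPINB2, 0.860 for PPP1R15A, 0.923 for UBE4B, 0.856 for CDKN1A, 0.926 for PLK2, 0.861 for PMAIP1, 0.889 for CD74, 0.895 for CDH2, 0.871 for CDH1, 0.871 for ENG and 0.871 for FOSL1. SERPINB2 was at 41.2 CPM in one library against 13.6 to 17.2 in the others, and FOSL1 at 174 against 95.2 to 105. In RBE vehicle it was 0.844 for INHBA, 0.890 for DUSP5, 0.922 for FLRT3, 0.878 for DERL2, 0.850 for UBXN7, 0.890 for PSMC3, 0.848 for HSPA8, 0.830 for CCN2, 0.873 for AQP1 and 0.864 for MT-ATP6.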

How the results depend on the processing

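The thinning of counts to the smallest library and the removal of GC and length trends were chosen only after the results were seen, and the other settings in this part were planned. No fold change of a named gene changed sign under any setting run for it. Among called lists, the HuCCT1 fibroblast median changed sign from -1.39 to 0.18 with no low-count filter and 0.20 with all 14 libraries in one fit, and the medians of some uncalled lists and the correlation between lines also changed sign. Counts of called genes stayed within 1.5 times their reported values under DESeq2, limma-voom, other scalings, other filters and each left-out library. They fell in a test against a 1.5-fold change, by its construction, to 1006 higher and 956 lower in HuCCT1, 1366 and 1290 in RBE, and 1859 and 1739 for the difference. They also fell with thinned counts, which test fewer genes at lower depth, to 2133 and 2042, 2083 and 1973, and 2072 and 2030, with 729 genes called in both lines in one direction, so depth limits how many small changes pass. The correlation between lines moved from -0.0029 to 0.0927 without a low-count filter, 0.0283 with a filter of 1 CPM and -0.035 with thinned counts, and the cause was not tested. With an estimated correlation, camera called 2 lists in HuCCT1, 7 in RBE and 6 for the difference. The estimate replaces the preset 0.01 and was 0.62 for HuCCT1 ribosomal proteins, 0.71 for RBE cholesterol genes and 0.76 for RBE mitochondrial mRNAs. It was 0.015 for HuCCT1 interferon genes and -0.030 for RBE NF-kB genes. A preset p for a list with a high estimate rests on a correlation that is too low. Calls also weakened where the estimate lay below the preset, so the size of the correlation alone does not explain the losses. For RBE apoptosis genes, with an estimate of -0.020, the camera adjusted p went from 0.024 to 0.14. For RBE NF-kB genes it went from 7.7e-09 to 0.011. How much of the loss the correlation explains was not tested.

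Leaving out each library in turn gave 3335 to 3568 higher and 3130 to 3421 lower genes in HuCCT1, 3796 to 4006 and 3779 to 3951 in RBE, and 3606 to 3950 and 3468 to 3733 for the difference. Called lists ranged from 13 to 16, 20 to 22 and 17 to 19, the correlation from -0.010 to 0.011, and genes shared in one direction from 1687 to 1913. Library totals without TMM factors gave 4440 higher and 2936 lower genes in HuCCT1 and 3141 and 4617 for the difference, and shifted the median of all genes in the difference to -0.136. The HuCCT1 G2/M and NRF2 lists, not called at an adjusted p of 0.055, passed under limma-voom (adjusted p = 0.025 and 0.029), library totals (0.033 and 0.043), no low-count filter (0.010 and 0.0055), the 1 CPM filter (0.040 for both) and without some single libraries (lowest 0.023 for both). The RBE MYC list, not called at 0.067, passed under limma-voom (0.028), no low-count filter (0.00074), the 1 CPM filter (0.044) and without vehicle replicate 3 (0.049) or CB-5339 replicate 3 (0.049). Of the named genes' calls, 51 were lost in the test against a 1.5-fold change and 12 with thinned counts.

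Replicate numbers share only a number here: same-numbered vehicle and CB-5339 libraries deviated with correlations of 0.052, -0.153 and -0.300 in HuCCT1 and 0.018, -0.015 and -0.027 in RBE, and not every sample correlated best with its own number. With the replicate number as a block, on libraries numbered 1 to 3, 3309 genes were higher and 3167 lower in HuCCT1, 3763 and 3821 in RBE, and 3531 and 3429 for the difference. In that fit the HuCCT1 histone call was lost (adjusted p = 0.051) and the G2/M (0.026) and NRF2 lists (0.049) passed. It also leaves out vehicle replicate 4, which alone gave 0.066 for histones and 0.025 for G2/M, so those moves cannot be put down to the block. NRF2 did not pass without that library alone (0.056).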

Other observations

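The YAP target list and the gene families in this part, and their tests, were chosen only after the results were seen. Families were taken as protein-coding genes sharing a symbol prefix, with at least 8 members, and tested with camera in each line, 199 families in HuCCT1 and 208 in RBE. In HuCCT1, 9 of 17 dual-specificity phosphatase genes (DUSP), which switch off MAP kinases, rose and 1 fell (median 0.74, camera adjusted p = 4.7e-05; adjusted p = 0.91 with an estimated correlation). In addition, 22 of 41 interleukin and receptor genes (IL) rose and 5 fell (median 0.61, adjusted p = 0.00016; adjusted p = 0.74 with an estimated correlation). Of 18 collagen genes (COL) 4 rose and 10 fell (median -0.73, adjusted p = 0.00036; adjusted p = 0.91 with an estimated correlation). Of 8 genes of the CCT chaperonin, which folds actin and tubulin, 7 rose (median 0.48, adjusted p = 0.021; adjusted p = 0.91 with an estimated correlation). Nucleoporin genes (NUP), which build the nuclear pore, rose in 15 of 22 cases in HuCCT1 (median 0.43, adjusted p = 0.0086; adjusted p = 0.74 with an estimated correlation) and fell in 18 of 22 in RBE (median -0.61, adjusted p = 0.00093; adjusted p = 0.77 with an estimated correlation).

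In RBE, 7 of 11 splicing factor genes of the SRSF family fell (median -0.64, camera adjusted p = 0.0010; adjusted p = 0.84 with an estimated correlation), and 6 of 8 CBX chromobox genes fell (median -0.58, adjusted p = 0.036; adjusted p = 0.77 with an estimated correlation). Of 31 kinesin genes (KIF) 7 rose and 18 fell (median -0.53, adjusted p = 3.2e-08; adjusted p = 0.23 with an estimated correlation), and of 9 matrix metalloproteinase genes (MMP) 7 rose and 1 fell (median 0.90, adjusted p = 0.0031; adjusted p = 0.82 with an estimated correlation). The directions were the same with library totals. None of these calls held with an estimated correlation. Differences between the lines were not tested for the families.

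One hypothesis for the rise of G1/S genes in HuCCT1 is that the CB-5339 cultures may have been less dense at harvest than the vehicle cultures, which would raise YAP targets. The median of 21 measured YAP targets in HuCCT1 was 0.06, with a camera p of 0.85. Of these targets 7 rose and 8 fell. Members going both ways decide nothing, so lower density cannot be told apart from other explanations. In RBE, where G1/S genes fell, 14 of 21 YAP targets rose and 2 fell (median 0.48, camera p = 7.1e-07, p = 0.0029 with an estimated correlation).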
